A study of Mus musculus with 35 samples.

How the data were processed

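Hepatocyte nuclei were purified by the INTACT method from livers of mice that carry a nuclear-envelope GFP tag under Albumin-Cre, and their open chromatin was profiled by ATAC-seq, per the labels' protocols. About 25000 nuclei per animal were transposed, libraries were amplified for 12 cycles and sequenced as paired ends on a HiSeq 4000. Livers were collected at ZT 9, and cachexia was defined by more than 10% weight loss. The 35 libraries fell into 9 groups of 4 cohorts as named in the labels: C26 (PBS, pre-cachexia, cachexia), NC26 and MC38 (PBS, weight-stable tumor) and 8025 (PBS, cachexia). The labels give each library its own animal, so p-values measure the spread between animals. Each group held 4 libraries except 8025 PBS with 3 (replicates 1, 2 and 4). Strain and cohort went together with tumor line, so cohorts were compared only as differences of effects against their own PBS group. Library names formed 2 series: all C26 libraries belonged to series A, all 8025 libraries to series B, and NC26 and MC38 to A for replicates 1 and 2 and to B for replicates 3 and 4.

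Reads were aligned by the authors to mm10 with BWA 0.7.5a-r405, handled with SAMtools, and turned into tag directories, peaks and an annotated table with HOMER, per the submitters' processing notes. Duplicate handling and peak calling settings are not given in the sources used here. The deposited signal values are tags in 400 bp around each of 177904 merged peaks, scaled by the authors to 10 M tags per library, per the file headers. Each value times its library's total tags gave whole read ends (100% of values within a tolerance of 0.05), where each end of a read pair counts as 0.5 tag. A peak was listed in all libraries for 30368 regions and in 1 library for 38482, and 37.1% of regions overlapped a neighbor. Total tags were 11.3 to 23.8 M, and 3.47 M in NC26 tumor replicate 1. Gene names are those of the nearest transcription start site in the authors' annotation, and a region may act on another gene.

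The design assumed counts and edgeR. The values were normalized, so the fallback set beforehand was used: limma-trend with robust empirical Bayes on log2 of the value plus a pseudocount of 1, after TMM scaling. filterByExpr (minimum count 10, minimum total 15) kept 177251 regions and removed 653. One model held all 9 groups and library series B as a covariate, and p-values were adjusted by Benjamini-Hochberg at 0.05 within each comparison. Fold changes on this scale understate changes of regions with low values. Comparisons, tests, named regions and the alternatives not listed as later were chosen before the data were examined. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 matplotlib 3.10.9 and the R package data.table in version 1.17.8.

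Named regions followed a fixed rule. For C26 and 8025 cachexia against PBS these were the 8 regions with the largest rise and the 8 with the largest fall, and for every other comparison 4 and 4. They had to pass the threshold and have average signal at or above the median, with 1 region per nearest gene and without predicted genes and small RNAs. Within cohorts they also had to show no overlap between libraries of both groups, a condition not applied to the differences of effects. In 4 libraries against 4, chance alone separates the groups completely in 2 of 70 orderings, counting both directions. The promoter region within 1 kb of the start sites of Nr1d1, Nr1d2, Lbp, Itih3 and Igfbp1 was named against PBS in every cohort, with up to 10 others of a panel of 38 genes by lowest adjusted p. Of these, 1 panel promoter that this rule selected in 2 comparisons was left out and not replaced. For gene lists the members with the lowest adjusted p served as examples. Their number of 3 per list, and describing the clock list where it was not called, were set after values were seen.

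A set of 23 gene lists was tested with camera (preset correlation 0.01, and an estimated correlation as alternative) on regions within 100 kb of a member's start site, adjusted over lists and comparisons. The lists covered circadian clock and clock output, acute phase, IL-6/STAT3 and NF-kB, AP-1 and immediate early, gluconeogenesis and glucocorticoid response, lipogenesis and glycolysis, cholesterol, PPARalpha and fatty acid oxidation, bile acids, xenobiotic metabolism, growth hormone and sex-biased genes, integrated stress and unfolded protein response, NRF2, urea cycle and amino acids, interferon and antigen presentation, cell cycle and hepatocyte identity. Marker lists covered macrophages, neutrophils, endothelium, stellate cells, cholangiocytes and lymphocytes. Counts of list regions refer to adjustment over all regions, and counts adjusted over the list alone are named as such. Promoter shares were compared with Fisher's exact test.

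Alternatives were RLE factors, library totals, loess offsets, no filter, DESeq2, only the cohorts compared, no library series, a replicate block, the promoter share of tags as covariate, autosomes, a threshold of 0.01, and leaving out each library. Alternatives added later are named with their effects. The fit was tested on simulated data with planted changes in 200 regions per size. It called 17 (8.5%) at 1.5-fold, 74 (37%) at 2-fold and 155 (77.5%) at 4-fold, and 11 of 260 calls were false (4.23%). The adjustment is stricter with so few changed regions than with the 24838 called in C26 cachexia. These shares therefore do not give the sensitivity of that comparison. Mean log2 changes of planted regions were 0.54, 0.86 and 1.76 where 0.58, 1 and 2 were planted. A simulated list shift of 0.3 was called with 0 other lists. Simulated regions varied independently of each other, so this does not measure false list calls where regions of a list vary together.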

Results

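Open chromatin of purified mouse hepatocyte nuclei was measured by ATAC-seq in 35 libraries from 9 groups in 4 cohorts. The C26 cohort (BALB/c) held PBS-injected, pre-cachexia and cachexia animals, n = 4 each. The NC26 (BALB/c) and MC38 (C57BL/6N) cohorts held PBS-injected and weight-stable tumor-bearing animals, n = 4 each. The 8025 cohort (C57BL/6N) held 3 PBS-injected and 4 cachexia animals. Each library had 11.3 to 23.8 M tags, except NC26 tumor replicate 1 with 3.47 M, and 37.3% to 62.9% of tags lay in the 177904 regions. Introns held 46.2% of regions, intergenic sequence 33.8% and promoters 12.2%. Replicates of a group varied 2.39 to 6.39 times as much as counting independent read ends would give (51 pairs). Both ends of a read pair can lie in 1 region, which by itself raises this ratio, so the excess over counting is smaller. Region values of replicates correlated with Spearman coefficients of 0.836 to 0.944.

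**Figure D1:**
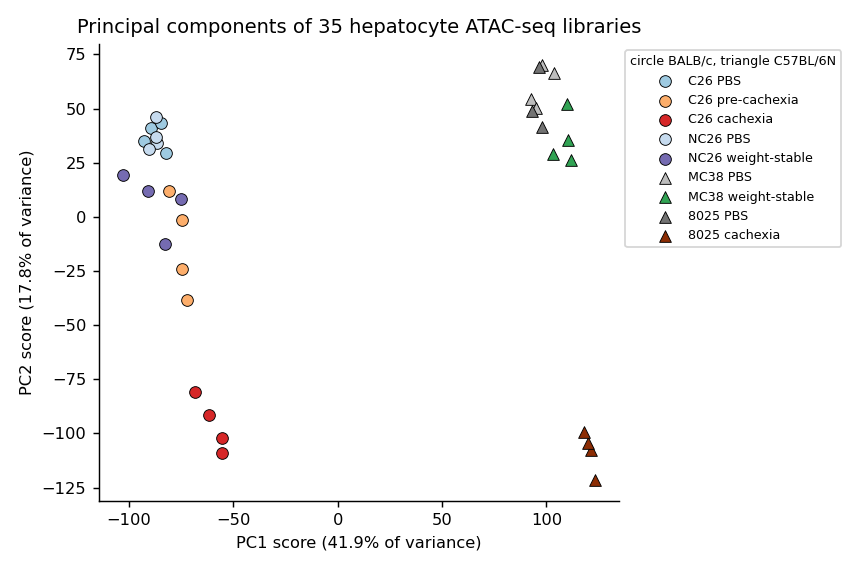
The horizontal axis is principal component 1 (41.9% of variance) and the vertical axis principal component 2 (17.8%), each point is 1 library of a group, and there are no error bars. BALB/c and C57BL/6N libraries lay apart along component 1, and cachexia libraries of C26 and 8025 lay lowest on component 2.

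In C26 cachexia, the metallothionein gene Mt2, which encodes a zinc-binding stress protein, had the largest rise among the regions named by the fixed rule. Its promoter region (chr8:94172469-94172869, mm10) went from 8.58 ± 4.16 to 270 ± 13.4 scaled tags (mean ± SD, n = 4 each), a 30.3-fold rise (log2 change 4.92 ± 0.39 SE, adjusted p = 2.2e-09). Regions at the acute phase genes Saa1 and Orm3 and nearest Fetub were also named. A region at the 3' end of Saa1 (chr7:46739308-46739708) rose from 3.24 ± 2.34 to 83.4 ± 26.9 (4.45 ± 0.81 SE, adjusted p = 0.00035), and an intergenic region nearest Fetub (chr16:22914347-22914747) from 4.13 ± 0.948 to 81.6 ± 32.1 (3.95 ± 0.46, adjusted p = 5.5e-07). The Orm3 promoter (chr4:63355841-63356241) rose from 7.47 ± 1.26 to 114 ± 12.2 (3.77 ± 0.3, adjusted p = 2.3e-11). Regions nearest Afdn (4.02 ± 0.34, adjusted p = 4.6e-10), Tab2 (3.68, adjusted p = 2.8e-09), Kank1 (3.62 ± 0.26, adjusted p = 2e-13) and Ctnna3 (3.52, adjusted p = 1.4e-08) were the other 4 named rises.

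The largest fall among the named regions in C26 cachexia was at the 3' end of Car3, which encodes a carbonic anhydrase abundant in male liver (chr3:14873061-14873461). It went from 98.6 ± 55.3 to 2.69 ± 2.53 scaled tags (n = 4 each), and the log2 value fell by 4.91 ± 0.6 SE (adjusted p = 2.2e-06). A region at the 3' end of Mup3, a major urinary protein gene (chr4:62082489-62082889), dropped from 37.8 ± 14.1 to 1.85 ± 0.96 (log2 fell by 3.73 ± 0.27, adjusted p = 1.9e-13). Regions nearest Olfr173, Eid2 and Tmem45a fell by 3.94 ± 0.25, 3.87 ± 0.27 and 3.74 (adjusted p = 5.2e-15, 6.3e-14 and 3.1e-12). Those nearest Rasgrp3, Nolc1 and Pcdh20 fell by 3.68, 3.57 and 3.49 (adjusted p = 3.5e-08, 1.7e-09 and 2.6e-06). Saa1, Orm3 and Mup3 belong to families of near-identical copies, so the copy from which their reads came is uncertain.

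Promoters of the fixed gene panel were tested in C26 cachexia too. That of Lcn2, which encodes an iron-sequestering secreted protein (chr2:32387603-32388003), went from 40 ± 3.11 to 196 ± 10.4 scaled tags (log2 change 2.27 ± 0.21 SE, n = 4 each, adjusted p = 4.6e-09). The promoter of Lbp, whose product carries bacterial lipopolysaccharide (chr2:158306359-158306759), went from 129 ± 9.43 to 269 ± 6.55 (1.06 ± 0.13, adjusted p = 1.4e-07). Itih3, an inter-alpha-trypsin inhibitor gene (chr14:30923414-30923814), rose by 1.19 ± 0.16 (adjusted p = 7.1e-07). Igfbp1, which encodes a fasting-induced carrier of insulin-like growth factors (chr11:7197489-7197889), rose by 1.24 ± 0.17 (88.1 ± 13.3 to 210 ± 34.9, adjusted p = 2.7e-06). The promoters of Saa2 (3.40 ± 0.55, adjusted p = 7.5e-05), Hp (1.05 ± 0.16, adjusted p = 1.5e-05), Cebpd (0.51, adjusted p = 0.00012), Per2 (0.33, adjusted p = 0.003) and Pck1 (0.35, adjusted p = 0.0033) also rose. Promoters of the clock repressors Nr1d1 (0.19 ± 0.1, adjusted p = 0.2) and Nr1d2 (0.16 ± 0.07, adjusted p = 0.1) did not pass, although Nr1d2 passed in 1 alternative fit (0.18, adjusted p = 0.02). The Socs3 promoter (0.63 ± 0.17, adjusted p = 0.0086) lost its call once the promoter share of each library was a covariate (0.46, adjusted p = 0.077). Socs2 (1.83, adjusted p = 0.012) lost it without PBS replicate 3 (1.41, adjusted p = 0.065) or cachexia replicate 4 (1.57, adjusted p = 0.054), and Orm2 (0.40, adjusted p = 0.012) without PBS replicate 4 (0.34, adjusted p = 0.066).

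**Figure D2:**
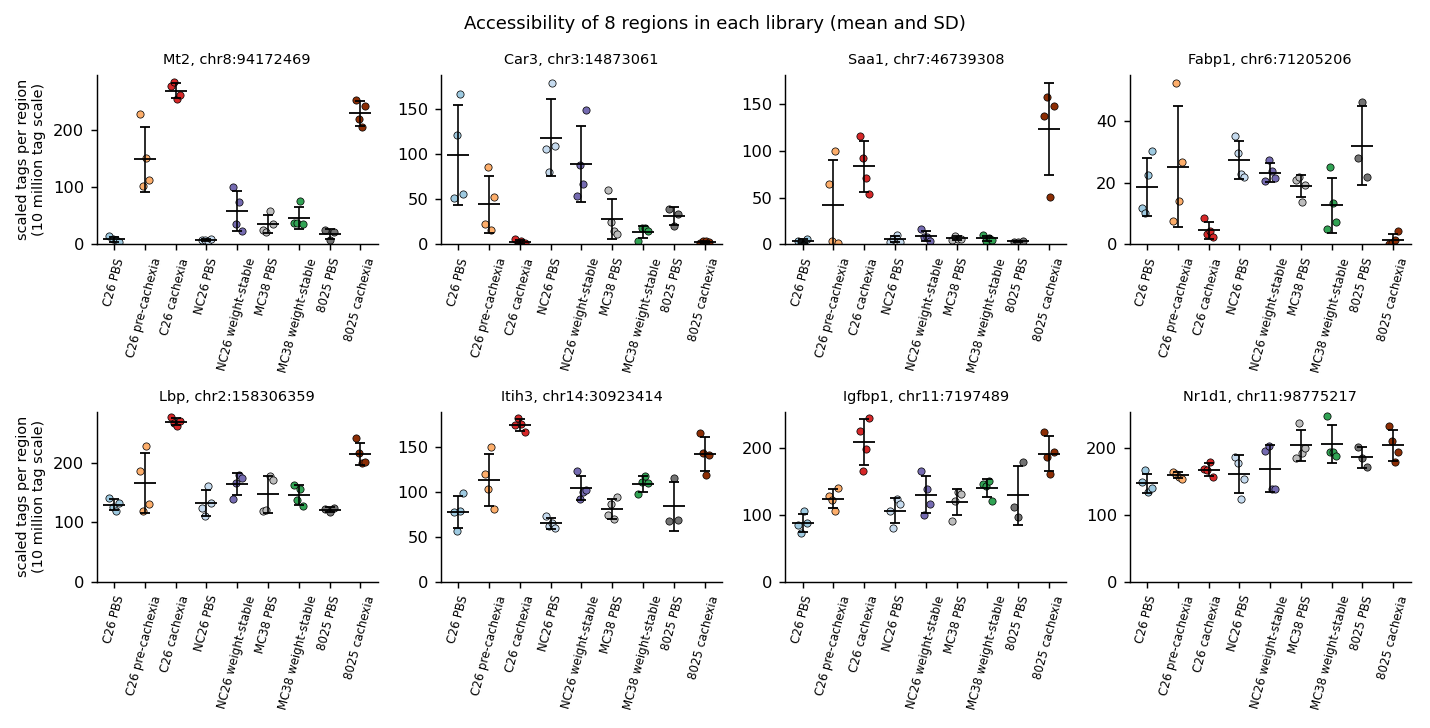
Each panel shows 1 region, with groups on the horizontal axis and scaled tags per 10 M on the vertical axis, points for libraries, and mean with SD as error bars. Mt2 reached 230 ± 21.7 in 8025 cachexia and 270 ± 13.4 in C26 cachexia, while Nr1d1 changed little in either.

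The acute phase list, the secreted liver proteins of inflammation, rose as a group in C26 cachexia. Of its 353 regions 188 rose and 4 fell, and adjusted over the list alone 215 rose and 10 fell. Of its genes 22 had only regions that rose, 4 had regions of both directions and 1 had none that passed (median log2 change 0.80). The list test gave adjusted p = 4e-41, and adjusted p = 0.0028 with an estimated correlation. Examples were Serpina3n, a protease inhibitor gene (a region at chr12:104414814, 3.34 ± 0.3 SE, 11.4 ± 2.72 to 126 ± 37.4, n = 4 each, adjusted p = 6e-11), and Apcs, the serum amyloid P gene (2.01 ± 0.22, adjusted p = 4.2e-09). The IL-6/STAT3 and NF-kB list had 117 regions higher and 16 lower of 507 (134 and 22 over the list alone; 14 genes only higher, 1 only lower, 6 both, 2 none; adjusted p = 4.4e-07). Its call held with adjusted p = 0.028 with an estimated correlation. Bcl3 rose by 1.69 ± 0.17 (22.7 ± 2.58 to 76.6 ± 18.1, adjusted p = 9.1e-10), and Osmr, a receptor subunit for oncostatin M, by 2.71 ± 0.29 (adjusted p = 4.3e-09).

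Lists of stress and amino acid genes had more regions that rose than fell in C26 cachexia, and none of these list calls held with an estimated correlation. The AP-1 and immediate early list had 45 higher and 12 lower of 236 regions (8 genes only higher, 4 only lower, 5 both, 3 none; adjusted p = 0.00034, and adjusted p = 0.093 with an estimated correlation). Fos, a transcription factor gene of the early response, rose from 70.7 ± 9.95 to 157 ± 23.2 (1.14 ± 0.12 SE, n = 4 each, adjusted p = 2.9e-09). The integrated stress response list had 35 higher and 2 lower of 235 (9 genes only higher, 1 only lower, 1 both, 15 none; adjusted p = 0.002, and adjusted p = 0.081 with an estimated correlation). In it Creld2 rose by 1.39 ± 0.18 (62.6 ± 11.1 to 164 ± 12.0, adjusted p = 4.4e-07) and Ddit4, an inhibitor of growth signalling, by 1.62 ± 0.21 (adjusted p = 8.7e-07). The urea cycle and amino acid list had 65 higher and 18 lower of 457 (10 genes only higher, 2 only lower, 6 both, 2 none; adjusted p = 0.003, and adjusted p = 0.56 with an estimated correlation). Mat1a, which makes S-adenosylmethionine, rose by 1.86 ± 0.19 (23.7 ± 2.85 to 89.3 ± 13.3, adjusted p = 1e-09). The gluconeogenesis and glucocorticoid list had 97 higher and 31 lower of 663 (12 genes only higher, 2 only lower, 9 both, 2 none; adjusted p = 0.0059, and adjusted p = 0.52 with an estimated correlation). Its members Mt1 (2.71 ± 0.25, adjusted p = 2.3e-10) and Got1 (0.78 ± 0.11, adjusted p = 1.6e-06) rose. The urea cycle call was lost without cachexia replicate 4 (adjusted p = 0.061).

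Lists of lipid and antioxidant genes had more regions that fell than rose in C26 cachexia, and none of these list calls held with an estimated correlation. The PPARalpha and fatty acid oxidation list had 17 higher and 49 lower of 295 regions (5 genes only higher, 10 only lower, 2 both, 7 none; adjusted p = 0.04, and adjusted p = 0.56 with an estimated correlation). Plin2, a lipid droplet coat gene, fell by 1.93 ± 0.22 SE (88.8 ± 9.58 to 23.5 ± 8.32, n = 4 each, adjusted p = 1.6e-08), and the promoter of the peroxisomal thiolase gene Acaa1b by 1.31 ± 0.16 (adjusted p = 1.1e-07). The lipogenesis and glycolysis list had 14 higher and 59 lower of 410 (3 genes only higher, 8 only lower, 4 both, 4 none; adjusted p = 0.018, and adjusted p = 0.63 with an estimated correlation). The promoter of Me1, malic enzyme, fell by 1.46 ± 0.22 (134 ± 11.4 to 48.9 ± 10.2, adjusted p = 2.7e-05), and Slc2a2, a glucose transporter gene, by 1.42 ± 0.21 (adjusted p = 2.6e-06). The NRF2 list had 4 higher and 23 lower of 204 (1 gene only higher, 4 only lower, 2 both, 7 none; adjusted p = 0.049, and adjusted p = 0.56 with an estimated correlation). Gsta1, a glutathione transferase gene, fell by 1.18 ± 0.18 (adjusted p = 6.9e-06), whereas Gclm rose by 1.94 ± 0.3. With only regions within 1 kb of a start site none of these 3 lists was called (lipogenesis adjusted p = 0.21, PPARalpha 0.48, NRF2 1), and NRF2 was not with RLE factors (0.051). The calls also depended on single libraries: lipogenesis was lost without PBS replicate 1 (adjusted p = 0.092) or cachexia replicate 3 (0.082). The PPARalpha list was lost without PBS replicate 1 (0.057) or cachexia replicates 2 (0.22) or 4 (0.12), and NRF2 without cachexia replicates 1 (0.075) or 3 (0.17) or PBS replicates 2 (0.13) or 3 (0.067).

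The clock and clock output list was not called in C26 cachexia (38 regions higher and 26 lower of 284; 8 genes only higher, 3 only lower, 6 both, 3 none; adjusted p = 0.57). An intron region of Per2, a core clock repressor, rose from 13.5 ± 1.41 to 64.9 ± 21.2 (2.12 ± 0.25 SE, n = 4 each, adjusted p = 4.4e-08), and Arntl, the core activator, rose by 1.19 ± 0.18 (adjusted p = 6e-06). Tef, a clock output factor, fell by 2.03 ± 0.33 (adjusted p = 1.4e-05). The clock list had a median of 0.03 and a mean of -0.008. The lists of growth hormone and sex-biased genes (55 higher, 76 lower of 582, adjusted p = 0.53), cholesterol (15 and 31 of 264, adjusted p = 0.42), bile acids (21 and 31 of 361, adjusted p = 0.47) and xenobiotic metabolism (22 and 34 of 305, adjusted p = 0.24) were not called. Interferon (19 and 6 of 168, adjusted p = 0.2), cell cycle (14 and 5 of 155, adjusted p = 0.64) and hepatocyte identity genes (43 and 35 of 523, adjusted p = 0.77) were not called either. Marker genes of other liver cells gave 2 higher and 0 lower of 45 regions for macrophages (median 0.225, adjusted p = 0.14), 5 and 5 of 42 for neutrophils (adjusted p = 0.48), and 10 and 9 of 154 for endothelium (adjusted p = 0.56). Stellate cell (1 and 4 of 45, adjusted p = 0.64), cholangiocyte (5 and 7 of 92, adjusted p = 0.81) and lymphocyte markers (0 and 5 of 47, adjusted p = 0.6) were not called.

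In total 12186 regions rose and 12652 fell in C26 cachexia among 177251 tested (14.0%), in limma at adjusted p of 0.05. The regions that rose lay nearest 5012 genes and those that fell nearest 4956. The median log2 change was 1.00 among regions that rose and -1.07 among those that fell, and 6078 and 7111 passed with a log2 change of at least 1. Of all tests 46070 had an unadjusted p under 0.05. edgeR called 25191 regions and DESeq2 28302.

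**Figure D3:**
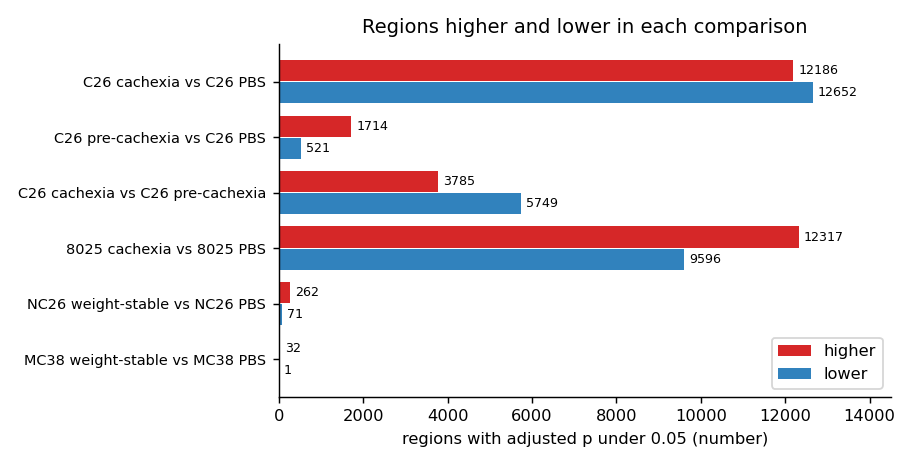
The vertical axis lists the comparisons and the horizontal axis gives the number of regions higher or lower, and there are no error bars because each bar is 1 count. C26 cachexia had 12186 higher and 12652 lower, 8025 cachexia 12317 and 9596, while NC26 had 262 and 71 and MC38 32 and 1.

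In C26 pre-cachexia, Mt2 had the largest rise among the named regions. Its promoter went from 8.58 ± 4.16 to 149 ± 56.9 scaled tags (log2 change 4 ± 0.39 SE, n = 4 each, adjusted p = 1.7e-06). An intron region of Fetub, which encodes a secreted protease inhibitor (chr16:22918591-22918991), rose from 9.59 ± 3.83 to 102 ± 27.4 (3.31 ± 0.4, adjusted p = 3.9e-05). Hs6st1 (3.19 ± 0.57, adjusted p = 0.0032) and Shisa5 (chr9:109027578-109027978, 3.05 ± 0.43, adjusted p = 0.00014) followed. Mup3 fell from 37.8 ± 14.1 to 8.75 ± 0.812 (fell by 1.91 ± 0.27, adjusted p = 2.8e-05), and Hspa8 and Cux2 fell by 1.78 each (adjusted p = 0.0062 and 0.0014). The promoter of Lcn2 rose from 40 ± 3.11 to 106 ± 45.7 (1.28 ± 0.21, adjusted p = 0.00081). Promoters of Lbp (0.31 ± 0.13, adjusted p = 0.28), Nr1d1 (0.12, adjusted p = 0.71) and Nr1d2 (0.13, adjusted p = 0.47) did not pass. Neither did Igfbp1 (0.50 ± 0.17, adjusted p = 0.15), which passed on the cohorts alone (adjusted p = 0.017) and with array weights (adjusted p = 0.031). Itih3 (0.54 ± 0.16, adjusted p = 0.08) passed without PBS replicate 4 (0.66, adjusted p = 0.023) or pre-cachexia replicate 4 (0.69, adjusted p = 0.016), in DESeq2 (adjusted p = 0.026) and with array weights (adjusted p = 0.031). The fall of Ppp1r3b by 1.75 (adjusted p = 0.033) was lost without PBS replicates 1 (adjusted p = 0.12), 3 (0.093) or 4 (0.052), or pre-cachexia replicates 1 (0.085), 2 (0.13) or 4 (0.065).

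Acute phase genes rose as a list in pre-cachexia, with 46 regions higher and 1 lower of 353 (113 and 6 over the list alone). Of its genes 16 had only regions that rose, 1 had both and 10 had none that passed (median 0.353, adjusted p = 2.8e-20, and adjusted p = 0.028 with an estimated correlation). Fgl1, which encodes a fibrinogen-like liver protein, rose from 20.8 ± 6.96 to 64.3 ± 9.62 (1.62 ± 0.22 SE, n = 4 each, adjusted p = 2.5e-05), and Orm1 from 61.2 ± 4.7 to 135 ± 25.7 (1.11 ± 0.16, adjusted p = 5.3e-05). The Saa1 and Lbp regions were high in only 2 of the 4 pre-cachexia libraries: Saa1, chosen here after its values were seen, had 64.2 and 100 scaled tags in replicates 1 and 3 and 3.16 and 1.16 in replicates 2 and 4. The Lbp promoter had 186 and 228 in replicates 1 and 3 and 118.5 and 131 in replicates 2 and 4, beside 118.1 to 140.5 in PBS libraries. The median of the acute phase list was -0.03 to 0.01 where replicate 3 was exchanged with a PBS library. The IL-6/STAT3 and NF-kB list had 17 higher and 0 lower (7 genes only higher, 16 none; adjusted p = 0.00034, and adjusted p = 0.098 with an estimated correlation). Bcl3 rose by 1.4 ± 0.17 (adjusted p = 1.7e-06) and Socs3, the feedback inhibitor of that pathway, by 1.32 ± 0.2 (adjusted p = 8e-05). Interferon and antigen presentation genes had 4 higher and 0 lower (adjusted p = 0.0025, and adjusted p = 0.091 with an estimated correlation). Irf1 rose from 78.1 ± 12.5 to 120 ± 3.03 (0.63 ± 0.11, adjusted p = 0.0011). The AP-1 list had 5 higher and 1 lower (4 genes only higher, 1 only lower, 15 none; adjusted p = 0.016, and adjusted p = 0.32 with an estimated correlation). Fos rose from 70.7 ± 9.95 to 126 ± 16.6 (0.83 ± 0.12, adjusted p = 4.6e-05) and Junb by 0.94 ± 0.15 (adjusted p = 0.00019).

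Another 3 lists were called lower in pre-cachexia with the preset correlation only. The urea cycle and amino acid list had 1 higher and 3 lower (median -0.23, adjusted p = 5.9e-08, and adjusted p = 0.22 with an estimated correlation). The lipogenesis list had 1 higher and 1 lower (median -0.135, adjusted p = 0.0014, and adjusted p = 0.52 with an estimated correlation). The gluconeogenesis and glucocorticoid list had 8 higher and 3 lower (median -0.154, adjusted p = 0.006, and adjusted p = 0.52 with an estimated correlation), and its member Mt1 rose by 2.04 ± 0.25 SE (n = 4 each, adjusted p = 3.2e-06). The PPARalpha (adjusted p = 0.71), cholesterol (0.4), bile acid (0.53), xenobiotic (0.16) and growth hormone lists (0.14) were not called. Macrophage markers had 0 higher and 0 lower of 45 (median 0.146, adjusted p = 0.4). The gluconeogenesis call was lost without PBS replicate 1 (adjusted p = 0.13) or pre-cachexia replicate 2 (0.054), and the AP-1 call without PBS replicates 2 (0.11) or 3 (0.17). With only regions within 1 kb of a start site the AP-1 (adjusted p = 0.079) and urea cycle lists (0.47) were not called, nor was the gluconeogenesis list (0.93), which also changed direction. In total 1714 regions rose (nearest 979 genes) and 521 fell (nearest 357), 1.26% of those tested, and this count of 2235 was 981, 861 and 1301 without PBS replicate 1, pre-cachexia replicate 1 and PBS replicate 3, and 4659 in DESeq2, 5836 with array weights and 4019 on the cohorts compared alone.

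From pre-cachexia to cachexia, the Lcn2 promoter went from 106 ± 45.7 to 196 ± 10.4 scaled tags (log2 change 0.98 ± 0.21 SE, n = 4 each, adjusted p = 0.0042), and the promoter of Cebpd, an acute phase transcription factor gene, rose by 0.45 ± 0.1 (adjusted p = 0.0019). An intron region of Hif3a, a hypoxia factor gene (chr7:17058132-17058532), rose from 8.38 ± 3.26 to 87.5 ± 46.8 (3.14 ± 0.58, adjusted p = 0.0013). Rhobtb1 (3.18 ± 0.62, adjusted p = 0.0023), Akr1d1 (2.94, adjusted p = 0.0026) and BB123696 (2.77, adjusted p = 0.0011) were the other named rises. Car3 fell from 44 ± 31.8 to 2.69 ± 2.53 (fell by 3.64 ± 0.6, adjusted p = 0.00045). The promoter of Hsd3b5, a male-specific steroid enzyme gene with close paralogs (chr3:98645413-98645813), fell from 41.8 ± 18.9 to 3.81 ± 3.23 (fell by 3.24 ± 0.43, adjusted p = 2.4e-05). Pnpt1 fell by 3.5 (adjusted p = 1.6e-05) and Rasgrp3 by 3.26 ± 0.36 (adjusted p = 1.9e-06). Another 6 panel promoters passed with all libraries but each lost its call without at least 1 of the 8.

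Amino acid genes rose from pre-cachexia to cachexia, with 86 regions higher and 1 lower of 457 in the urea cycle list (130 and 6 over the list alone). Of these genes 16 had only regions that rose, 1 had only regions that fell and 3 had none (median 0.362, adjusted p = 2.4e-18, and adjusted p = 0.031 with an estimated correlation). Mat1a rose from 35.2 ± 9.24 to 89.3 ± 13.3 (1.35 ± 0.19 SE, n = 4 each, adjusted p = 7e-06), and Hal, the histidine-degrading enzyme gene, from 69.3 ± 12.2 to 115 ± 5.59 (0.73 ± 0.12, adjusted p = 0.00014). The acute phase list had 57 higher and 1 lower (16 genes only higher, 1 only lower, 10 none; median 0.43, adjusted p = 3.3e-23, and adjusted p = 0.028 with an estimated correlation). Serpina3n rose from 23.9 ± 12.9 to 136 ± 41.4 (2.59 ± 0.31, adjusted p = 5.2e-07) and a region at the 3' end of Itih3 from 82.4 ± 12.6 to 166 ± 13.6 (1.01 ± 0.12, adjusted p = 3.3e-07). The integrated stress response list had 23 higher and 0 lower (6 genes only higher, 20 none; adjusted p = 8.1e-05, and adjusted p = 0.028 with an estimated correlation). Sesn2, a growth-restraining stress gene, rose from 30.8 ± 9.32 to 101 ± 17.4 (1.72 ± 0.25, adjusted p = 3.8e-05), and Atf4, the main transcription factor of that response, from 48.2 ± 8.09 to 78.0 ± 6.3 (0.69 ± 0.15, adjusted p = 0.0028).

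Between these stages the gluconeogenesis and glucocorticoid list had 81 regions higher and 13 lower of 663 (17 genes only higher, 3 only lower, 3 both, 2 none; median 0.271, adjusted p = 2.6e-10, and adjusted p = 0.081 with an estimated correlation). Irs2, an insulin receptor substrate gene, rose from 16.2 ± 6.12 to 54.9 ± 21.4 (1.7 ± 0.24 SE, n = 4 each, adjusted p = 7.2e-06), and Klf9, a glucocorticoid target, from 34.8 ± 2.22 to 87.7 ± 6.86 (1.31 ± 0.19, adjusted p = 2.6e-05). The PPARalpha list had 2 higher and 35 lower (1 gene only higher, 8 only lower, 15 none; adjusted p = 0.0021, and adjusted p = 0.35 with an estimated correlation). Fabp1, the liver fatty acid carrier gene, fell from 32 ± 21.5 to 2.48 ± 0.782 (fell by 3.07 ± 0.36, adjusted p = 1.1e-06). Growth hormone and sex-biased genes had 22 higher and 48 lower (5 genes only higher, 11 only lower, 1 both, 12 none; adjusted p = 0.011, and adjusted p = 0.52 with an estimated correlation). In that list Slco1a1, a male-biased transporter gene, fell by 2.42 ± 0.29 (adjusted p = 5.6e-07) and Cyp17a1 rose by 2.72 ± 0.34 (adjusted p = 9e-07). IL-6/STAT3 (36 higher, 7 lower, adjusted p = 0.0021, and adjusted p = 0.18 with an estimated correlation) and AP-1 genes (13 and 3, adjusted p = 0.012, and adjusted p = 0.3 with an estimated correlation) also rose. Gadd45g, a DNA-damage and cytokine response gene, rose by 2.2 ± 0.29 (adjusted p = 8.4e-06) and Jund by 1.13. Macrophage markers had 1 higher and 0 lower (median 0.077, adjusted p = 0.35). In total 3785 regions rose and 5749 fell (5.38%). That count of 9534 was 4347 without pre-cachexia replicate 2, 5925 without pre-cachexia replicate 4, 5174 without cachexia replicate 4 and 4355 with the promoter covariate, and the growth hormone call was lost without pre-cachexia replicate 3 (adjusted p = 0.051). With only regions within 1 kb of a start site the growth hormone (adjusted p = 0.37) and PPARalpha lists (0.56) were not called.

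Of the regions called in pre-cachexia, 1414 of 1714 higher and 398 of 521 lower were called in the same direction in C26 cachexia, against 117.8 and 37.19 by independent overlap. Both comparisons used the same 4 PBS libraries. Simulated unchanged groups with shared controls gave 0 regions called in both (10 runs), a Spearman coefficient between the 2 sets of log2 changes of 0.467 to 0.473 and a covariance of 0.0499 to 0.0507, beside 0.557 and 0.142 in the samples. With the PBS libraries divided 2 and 2 between the comparisons, the regions called in both were 1302 of 3941 called in pre-cachexia, 1081 of 3112, 1149 of 3097, 816 of 1386, 410 of 497 and 403 of 521 in the 6 divisions, with Spearman coefficients of 0.237 to 0.374 and covariances of 0.0812 to 0.117.

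In 8025 cachexia, the regions named by the fixed rule included those of the acute phase genes Saa1 and Serpina3n and of the cytokine feedback gene Socs3. The Saa1 region went from 3.08 ± 0.626 to 123 ± 49.5 scaled tags (log2 change 4.81 ± 0.87 SE, n = 3 PBS and 4 cachexia, adjusted p = 0.00044), and the Fetub region rose by 4.59 ± 0.5 (adjusted p = 3.1e-07). A region nearest Socs3 (chr11:117934179-117934579) went from 8.3 ± 2.76 to 164 ± 28.6 (4.18 ± 0.41, adjusted p = 2.6e-08). A region of Serpina3n (chr12:104415527-104415927) went from 9.76 ± 1.62 to 128 ± 26.8 (3.57 ± 0.33, adjusted p = 1.8e-09). The Mt2 promoter rose from 17.7 ± 8.48 to 230 ± 21.7 (3.75 ± 0.42, adjusted p = 9.2e-07). Shisa5 (4.33 ± 0.46, adjusted p = 2.2e-07), Arap3 (4.11, adjusted p = 3.8e-10) and Ralgps2 (3.66, adjusted p = 5e-10) were also named. The largest fall among the named regions was at the 3' end of Fabp1 (chr6:71205206-71205606), from 32.1 ± 12.7 to 1.52 ± 1.97 (fell by 3.94 ± 0.53, adjusted p = 8e-06). Thrsp, a lipogenesis regulator gene (chr7:97411060-97411460), dropped from 44.3 ± 25.2 to 2.64 ± 1.91 (fell by 3.66 ± 0.78, adjusted p = 0.0023). An exon region of Pklr, liver pyruvate kinase (chr3:89147919-89148319), dropped from 110 ± 83.0 to 9.11 ± 2.19 (fell by 3.10 ± 0.57, adjusted p = 0.00048). Eid2 fell by 3.69 ± 0.29 (adjusted p = 2e-11), Hsd3b5 by 3.56 ± 0.46 (adjusted p = 4.6e-06) and Car3 by 3.16 ± 0.65 (adjusted p = 0.0015). Hcn3 fell by 3.69 (adjusted p = 0.0012) and Atp5g3 by 3.17 (adjusted p = 0.00015).

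Panel promoters in 8025 cachexia rose for Lcn2 (34.6 ± 7.67 to 184 ± 14.2, log2 change 2.40 ± 0.23 SE, n = 3 and 4, adjusted p = 1.5e-08), Lbp (0.82 ± 0.14, adjusted p = 5.4e-05), Itih3 (0.79 ± 0.17, adjusted p = 0.0011), Saa2 (3.28 ± 0.59) and Saa1 (2.47). Nr1d1 (0.13, adjusted p = 0.5) and Nr1d2 (-0.05, adjusted p = 0.75) did not pass. Igfbp1 rose by 0.61 ± 0.18 (adjusted p = 0.022), which did not pass without PBS replicate 1 (0.53, adjusted p = 0.11), PBS replicate 2 (0.43, adjusted p = 0.19) or cachexia replicate 1 (0.53, adjusted p = 0.075). The other 6 panel promoters that passed each lost their call without at least 1 of the 7 libraries.

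Lipogenesis and glycolysis genes fell as a list in 8025 cachexia, with 6 regions higher and 121 lower of 410 (10 and 152 over the list alone). Of the genes 14 had only regions that fell, 4 had both directions, 1 had none and 0 had only regions that rose (median -0.47, adjusted p = 1.3e-17, and adjusted p = 0.031 with an estimated correlation). The Slc2a2 promoter fell from 108 ± 13.8 to 39.3 ± 7.92 (fell by 1.45 ± 0.17 SE, n = 3 and 4, adjusted p = 1.5e-07). Srebf1, the main lipogenic transcription factor gene, fell from 38.7 ± 16.3 to 8.47 ± 4.21 (fell by 2.09 ± 0.28, adjusted p = 1.1e-06). Hepatocyte identity genes had 18 higher and 52 lower of 523 (2 genes only higher, 7 only lower, 6 both, 2 none; adjusted p = 0.0028, and adjusted p = 0.18 with an estimated correlation). A region of Cebpa, a hepatocyte transcription factor gene, fell from 198 ± 30.7 to 44.8 ± 13.3 (fell by 2.16 ± 0.23, adjusted p = 4.1e-07), and the Foxa2 promoter from 147 ± 33.7 to 75.4 ± 14.0 (fell by 0.95 ± 0.14, adjusted p = 8e-06). PPARalpha genes had 9 higher and 46 lower (3 genes only higher, 9 only lower, 1 both, 11 none; adjusted p = 8.1e-05, and adjusted p = 0.2 with an estimated correlation), although Cpt1a, the gatekeeper of mitochondrial fatty acid import, rose from 8.94 ± 4.42 to 47 ± 4.45 (2.36 ± 0.28, adjusted p = 1.1e-07). Bile acid genes had 12 higher and 36 lower (5 genes only higher, 8 only lower, 2 both, 1 none; adjusted p = 0.0012, and adjusted p = 0.29 with an estimated correlation), with Slco1a1 lower by 2.05 ± 0.21 (adjusted p = 3.5e-09). Growth hormone and sex-biased genes had 25 higher and 61 lower (8 genes only higher, 6 only lower, 6 both, 9 none; adjusted p = 0.0065, and adjusted p = 0.5 with an estimated correlation). Their call was lost without PBS replicate 2 (adjusted p = 0.084).

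In 8025 cachexia, acute phase genes had 162 regions higher and 3 lower of 353 (184 and 6 over the list alone; 24 genes only higher, 2 both, 1 none; median 0.719, adjusted p = 2.8e-31, and adjusted p = 0.0082 with an estimated correlation). Apcs rose from 32.9 ± 7.9 to 117 ± 10.1 (1.82 ± 0.17 SE, n = 3 and 4, adjusted p = 7.5e-10). IL-6/STAT3 and NF-kB genes had 104 higher and 19 lower of 507 (15 genes only higher, 1 only lower, 4 both, 3 none; adjusted p = 4.7e-06, and adjusted p = 0.035 with an estimated correlation). The Osmr promoter rose from 7.51 ± 0.852 to 86.0 ± 3.42 (3.36 ± 0.31, adjusted p = 5.2e-10). AP-1 genes had 27 higher and 10 lower (12 genes only higher, 2 only lower, 1 both, 5 none; adjusted p = 0.039, and adjusted p = 0.43 with an estimated correlation), and Jund rose by 2.6 ± 0.25 (adjusted p = 6.1e-10). Macrophage markers stood beside these lists with 5 higher and 1 lower of 45 (median 0.617, adjusted p = 0.00081, and adjusted p = 0.29 with an estimated correlation). Csf1r, the receptor for a macrophage growth factor, rose from 16.5 ± 2.96 to 37.9 ± 5.74 (1.16 ± 0.28, adjusted p = 0.0032). The AP-1 call was lost without cachexia replicates 1 (adjusted p = 0.08) or 3 (0.057) or PBS replicate 4 (0.13), with a replicate block (0.067) and with only regions within 1 kb of a start site (0.8).

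The clock and clock output list was not called in 8025 cachexia (18 regions higher and 47 lower of 284; 2 genes only higher, 8 only lower, 4 both, 6 none; adjusted p = 0.18). Hlf, a clock output factor gene, fell from 42.6 ± 1.52 to 9.92 ± 1.75 (fell by 2.01 ± 0.23 SE, n = 3 and 4, adjusted p = 3.4e-08), while Nfil3, a repressor of the same sites, rose from 3.33 ± 0.526 to 48.5 ± 11.8 (3.49 ± 0.43, adjusted p = 1.8e-07). Also not called were gluconeogenesis (62 higher, 36 lower, median -0.024, mean 0.103, adjusted p = 0.84), urea cycle (27 and 25, adjusted p = 0.77), integrated stress response (26 and 3, adjusted p = 0.13) and NRF2 genes (5 and 15, adjusted p = 0.22). Nor were cholesterol (17 and 29, adjusted p = 0.21), xenobiotic (13 and 29, adjusted p = 0.2), interferon (14 and 6, adjusted p = 0.41) and cell cycle genes (11 and 5, adjusted p = 0.91). Markers of neutrophils (4 higher and 0 lower, adjusted p = 0.35), endothelium (10 and 5, adjusted p = 0.48), stellate cells (1 and 6, adjusted p = 0.89), cholangiocytes (8 and 2, adjusted p = 0.4) and lymphocytes (1 and 5, adjusted p = 0.54) were not called. In total 12317 regions rose (nearest 5091 genes) and 9596 fell (nearest 3888), 12.4% of those tested, with 9148 and 4405 at a log2 change of at least 1. The count of 21913 was 12915 without PBS replicate 2, and edgeR called 24893 and DESeq2 28016.

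**Figure D4:**
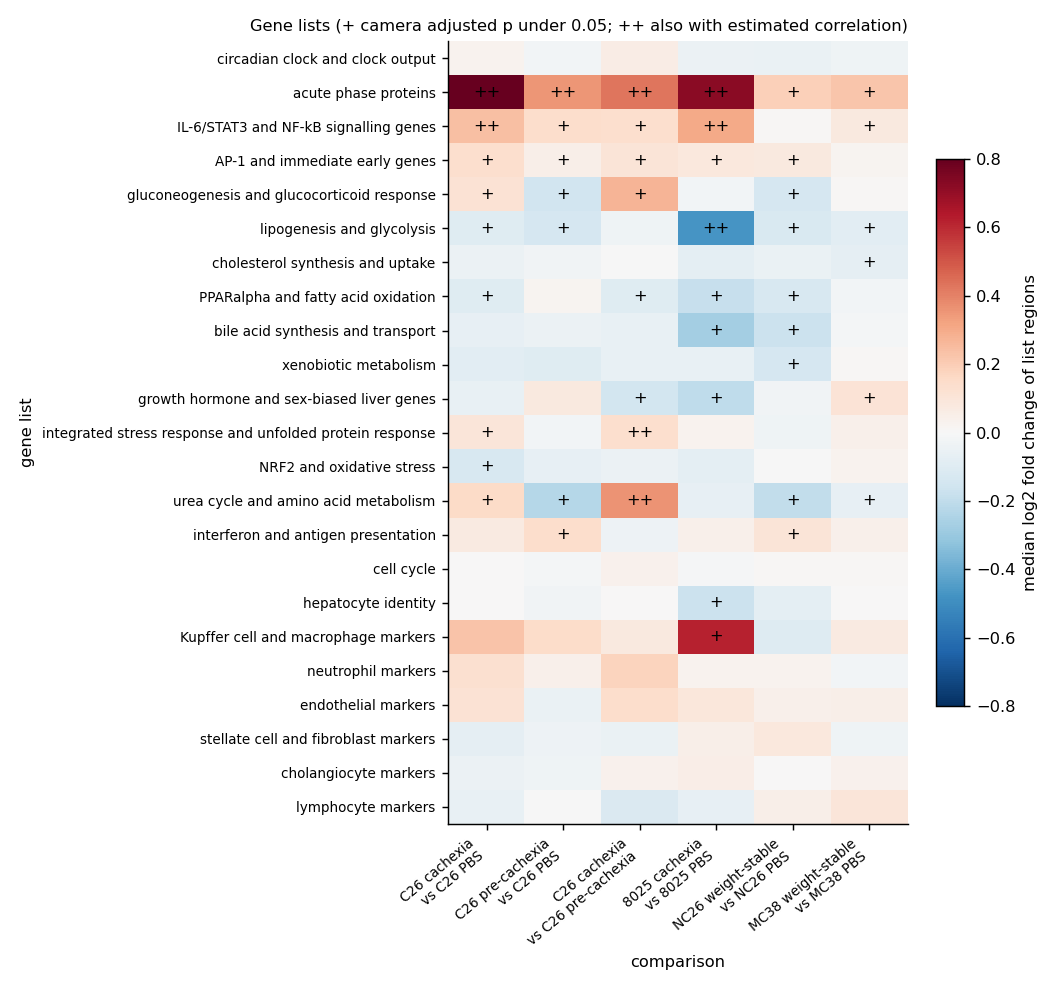
Rows are gene lists, columns are comparisons, and color is the median log2 change of the list's regions on a scale from -0.8 to 0.8, without error bars; signs mark list calls with the preset and the estimated correlation. Acute phase genes were 0.80 in C26 and 0.72 in 8025 cachexia, and lipogenesis was -0.47 in 8025.

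C26 and 8025 cachexia changed many of the same genes. Regions higher in both numbered 5578, nearest 2635 genes, against 846.8 by independent overlap, and included those of Mt2, Saa1 and Fetub. Regions lower in both numbered 4713, nearest 2216 genes, against 685, and included those of Car3 and Eid2. Opposite directions were called in 5 and 20 regions. Log2 changes of the 2 models correlated across regions with a Spearman coefficient of 0.546. The difference of effects, C26 minus 8025, passed in 180 regions (49 higher, 131 lower). Sntg2, a syntrophin gene (difference -2.94 ± 0.4 SE, adjusted p = 0.00044, n = 4, 4, 4 and 3), rose in 8025 from 2.07 ± 0.711 to 18.2 ± 5.36. Pak6 (-2.88 ± 0.43), Map3k13 (-2.7 ± 0.4) and Pus7 (-2.63 ± 0.39) also differed. Lrrc32 differed in the other direction (1.6 ± 0.25, adjusted p = 0.0018), from 28.9 ± 5.94 to 135 ± 21.4 in C26 cachexia. The acute phase list did not differ (0 regions, median 0.083, adjusted p = 0.13). The lipogenesis list did (median 0.294, adjusted p = 2.5e-12, and adjusted p = 0.089 with an estimated correlation), as did urea cycle genes (median 0.182, adjusted p = 8.2e-05, and adjusted p = 0.41 with an estimated correlation). Hepatocyte identity genes differed likewise (median 0.183, adjusted p = 5.2e-05, and adjusted p = 0.067 with an estimated correlation). The count of 180 was 407 without 8025 cachexia replicate 1 and from 64 to 106 without any of C26 PBS replicates 2, 3 and 4, C26 cachexia replicates 2, 3 and 4, 8025 PBS replicates 1 and 2, or 8025 cachexia replicates 2, 3 and 4. It was 17 with the promoter covariate, 434 on the cohorts compared alone, 732 with a pseudocount of 5, 799 in DESeq2 and 905 with array weights.

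**Figure D5:**
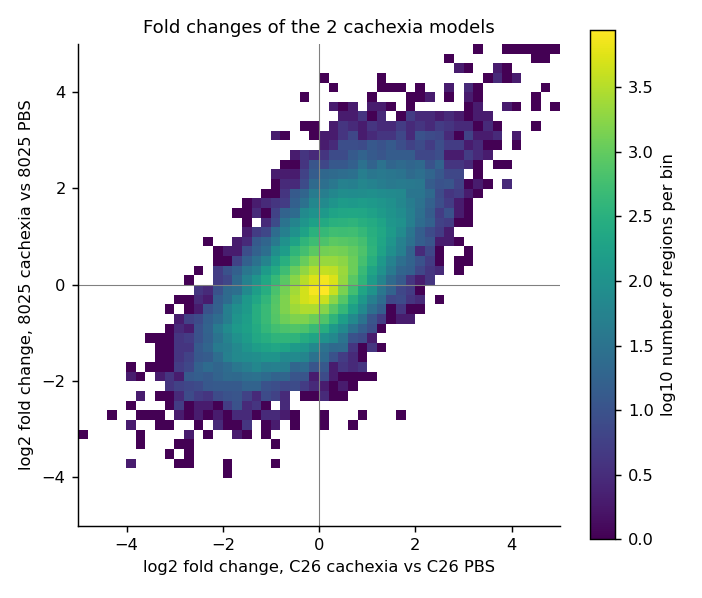
The horizontal axis is the log2 change in C26 cachexia and the vertical axis that in 8025 cachexia, color is the number of regions, and there are no error bars. The changes correlated with a Spearman coefficient of 0.546, with 5578 regions higher and 4713 lower in both.

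In weight-stable NC26 tumor-bearing mice few regions changed. Ctnna3, a catenin gene, rose from 2.88 ± 2.14 to 25.5 ± 11 scaled tags (log2 change 2.82 ± 0.37 SE, n = 4 each, adjusted p = 0.00014). The Mt2 promoter rose from 7.67 ± 1.2 to 58.7 ± 35.2 (2.58 ± 0.39, adjusted p = 0.002), and Afdn by 2.26 ± 0.31 (adjusted p = 0.00054). A region nearest Eid2 fell from 29.8 ± 8.99 to 8.48 ± 4.43 (fell by 1.80 ± 0.32, adjusted p = 0.0038). Fos rose from 72.4 ± 9.12 to 123 ± 15.5 (0.75 ± 0.12, adjusted p = 0.00085), and the promoter of Irf1, an interferon response factor gene, from 70.7 ± 11.6 to 115 ± 4.15 (0.71 ± 0.11, adjusted p = 0.00087). Promoters of Lbp (0.32 ± 0.13, adjusted p = 0.36), Igfbp1 (0.28, adjusted p = 0.57), Nr1d1 (0.07, adjusted p = 0.86) and Nr1d2 (0.00) did not pass. The other 4 regions of the fixed rule lost their call without at least 1 library, and with only 1 library series (2 libraries per group) Mt2 (series B, adjusted p = 0.37), Irf1 (B, 0.34), Afdn (A, 0.1), Fos (A, 0.097) and Eid2 (A, 0.066, and B, 0.24) did not pass. Itih3 (0.67 ± 0.16, adjusted p = 0.054) passed without tumor replicate 2 (adjusted p = 0.032) and in DESeq2 (adjusted p = 0.035).

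Lists in NC26 were called with few regions passing alone. Acute phase genes had 6 higher and 1 lower (30 and 5 over the list alone; 3 genes only higher, 1 both, 23 none; median 0.188, adjusted p = 1.1e-07, and adjusted p = 0.24 with an estimated correlation). AP-1 genes had 2 higher and 0 lower (adjusted p = 0.0018, and adjusted p = 0.16 with an estimated correlation), and interferon genes 1 and 0 (median 0.104, adjusted p = 0.0021, and adjusted p = 0.089 with an estimated correlation). Urea cycle genes were lower (median -0.2, 0 regions passing, adjusted p = 5.9e-07, adjusted p = 0.28 with an estimated correlation, and adjusted p = 0.14 with only regions within 1 kb of a start site). The gluconeogenesis, lipogenesis, PPARalpha, bile acid and xenobiotic lists were called lower with the preset correlation only, and each lost its call without at least 1 library. Macrophage, neutrophil and the other 4 marker lists were not called. In total 262 regions rose and 71 fell. The count of 333 was 153, 185, 182 and 221 without PBS replicates 1, 2, 3 and 4, and 80, 1184 and 524 without tumor replicates 1, 2 and 3. The balance of directions moved too: 590 higher and 594 lower without tumor replicate 2, 280 and 244 without tumor replicate 3, 30 and 101 in library series A alone, 74 and 4 on this cohort alone, 136 and 9 in edgeR, and 141 and 14 with array weights.

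In weight-stable MC38 tumor-bearing mice 32 regions rose and 1 fell. A region nearest Prune1 rose from 17.0 ± 8.84 to 58.9 ± 14.2 (log2 change 1.82 ± 0.24 SE, n = 4 each, adjusted p = 0.00036). A region nearest Nampt, which encodes an enzyme of NAD synthesis, rose from 7.0 ± 2.15 to 26.1 ± 8.21 (1.76 ± 0.27, adjusted p = 0.0021). Promoters of Lbp (0.01), Itih3 (0.43, adjusted p = 0.62), Igfbp1 (0.25, adjusted p = 0.89), Nr1d1 (0.01) and Nr1d2 (-0.05, adjusted p = 0.96) did not pass. Acute phase genes had 2 higher and 0 lower regions (11 and 0 over the list alone; median 0.223, adjusted p = 4.9e-10, and adjusted p = 0.16 with an estimated correlation). Another 5 lists were called with the preset correlation only, and each lost its call without at least 1 library. The other 3 regions of the fixed rule lost their call without at least 1 library, Prune1 did not pass in library series A alone (adjusted p = 0.13) or on this cohort alone (0.077), and Nampt in neither series alone (A, 0.24, and B, 0.085). limma found an unadjusted p under 0.05 in 11197 regions, edgeR called 37 regions and DESeq2 249. The count of 33 was 58, 15 and 18 without PBS replicates 1, 2 and 4, and 67, 10, 19 and 8 without tumor replicates 1, 2, 3 and 4. It was 10 on this cohort alone, 12 with the promoter covariate, 16 and 11 in series A and B alone and 51 with array weights.

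Effects of C26 cachexia and NC26 tumors differed in 3794 regions (1826 higher, 1968 lower in C26). Kank1, an actin regulator gene, differed by 3.31 ± 0.37 SE (n = 4 each, adjusted p = 8.1e-07), with 117 ± 15.6 scaled tags in C26 cachexia and 11.9 ± 3.33 with NC26 tumors. Serpina3n (chr12:104415156) differed by 3.33 ± 0.52 (adjusted p = 0.0003), Hif3a by 3.66 ± 0.82 (adjusted p = 0.017) and the Lcn2 promoter by 1.55 ± 0.3 (adjusted p = 0.0044). Car3 (-4.46 ± 0.85, adjusted p = 0.0054), Olfr173 (-3.55 ± 0.36, adjusted p = 3.5e-08), Pcdh20 (-3.51 ± 0.65, adjusted p = 0.0031) and Rasgrp3 (-3.46 ± 0.51, adjusted p = 0.00038) differed in the other direction. Acute phase genes differed as a list (42 regions higher, 0 lower, median 0.642, adjusted p = 1e-25, and adjusted p = 0.025 with an estimated correlation). Urea cycle (28 and 0, adjusted p = 4.3e-10, and adjusted p = 0.14 with an estimated correlation), gluconeogenesis (33 and 4, adjusted p = 1.2e-06, and adjusted p = 0.15 with an estimated correlation) and integrated stress response genes (9 and 0, adjusted p = 0.0006, and adjusted p = 0.067 with an estimated correlation) were higher too. The count was 2135 without C26 cachexia replicate 4, 2152 without NC26 PBS replicate 1 and 2195 with the promoter covariate.

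Effects of 8025 cachexia and MC38 tumors differed in 3009 regions (1615 higher, 1394 lower in 8025). Arap3 (4.27 ± 0.5 SE, n = 4, 3, 4 and 4, adjusted p = 6.6e-06), Fetub (3.56 ± 0.68, adjusted p = 0.0054), Socs3 (3.45 ± 0.55, adjusted p = 0.0011) and the Lcn2 promoter (1.92 ± 0.31, adjusted p = 0.0012) were higher. Hsd3b5 was lower by 3.57 ± 0.63 (adjusted p = 0.0027). Acute phase genes differed as a list (42 higher, 0 lower, median 0.506, adjusted p = 2.1e-18, and adjusted p = 0.065 with an estimated correlation). Lipogenesis genes were lower (0 higher, 17 lower, median -0.383, adjusted p = 1.6e-11, and adjusted p = 0.089 with an estimated correlation), as were growth hormone and sex-biased genes (2 and 17, adjusted p = 4.1e-06, and adjusted p = 0.14 with an estimated correlation). Macrophage markers differed in the list test with 0 regions passing (median 0.518, adjusted p = 0.0014, and adjusted p = 0.3 with an estimated correlation). The count was 1793 and 1139 without 8025 PBS replicates 1 and 2 and 1730 without MC38 tumor replicate 3, and 6.0e+03 in DESeq2, 4745 with array weights and 4614 with a pseudocount of 5.

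Of the 262 regions higher in NC26, 230 were also higher in C26 cachexia, against 18.01 by independent overlap, among them those of Mt2 and Ctnna3. Of the 71 lower, 20 were lower in C26 cachexia (5.068). Pre-cachexia and NC26 shared 174 higher regions (2.534). Of the 32 higher in MC38, 27 were also higher in 8025 cachexia (2.224), and NC26 and MC38 shared 5 (0.0473). Pre-cachexia and 8025 cachexia shared 997 higher and 221 lower regions, against 119.1 and 28.21.

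Promoter regions made up different shares of the changed regions in the 2 cachexia models. In C26 cachexia they were 14.4% of regions that rose, 4.33% of those that fell and 12.7% of unchanged regions (Fisher exact p = 2.8e-07 and 1.53e-214). In 8025 cachexia they were 5.59% of regions that rose, 9.07% of those that fell and 13.0% of unchanged regions (Fisher exact p = 1.25e-151 and 5.52e-31). The share of region tags in promoters was 34.3 ± 0.542% in C26 PBS and 35.5 ± 0.39% in C26 cachexia libraries (mean ± SD, n = 4 each), and 34.9 ± 0.793% and 34.2 ± 1.13% in 8025 (n = 3 and 4). Promoters that rose in C26 included those of Mt2, Orm3 and Lcn2, and promoters that fell in 8025 included those of Slc2a2 and Foxa2. The C26 share of regions that rose was below that of unchanged regions with a log2 change of at least 1 (3.93%), with loess offsets (9.945%), library totals (12.65%) and the promoter covariate (8.506%). Fisher's test treats regions as independent, although 37.1% overlapped a neighbor.

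Of 207 list tests, 33 had a median, mean and test that differed in sign, and 0 of these were among the 68 called. In the within-cohort comparisons 48 list calls with the preset correlation became 9 with an estimated correlation. Those 9 were acute phase genes in 4 comparisons, IL-6/STAT3 genes in C26 and 8025 cachexia, lipogenesis in 8025, and urea cycle and integrated stress response genes between the C26 stages.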

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

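The 2 tests on macrophage markers were chosen only after the result was seen, and the other tests before.

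Effects of tumor-bearing groups differed by a test of the difference itself in 3794 regions between C26 cachexia and NC26, 3009 between 8025 cachexia and MC38, and 180 between C26 and 8025 cachexia (limma). C26 exceeded NC26 at Hif3a (3.66 on the log2 scale), Myoz2 (3.34), Serpina3n (3.33), Kank1 (3.31), Lcn2 (1.55), Hp (0.83), Cps1 (0.65), Cebpd (0.54) and Pck1 (0.48). It was below NC26 at Car3 (-4.46), Olfr173 (-3.55), Pcdh20 (-3.51) and Rasgrp3 (-3.46). 8025 exceeded MC38 at Saa1 (4.88), Arap3 (4.27), Fetub (3.56), Socs3 (3.45) and Lcn2 (1.92). It was below MC38 at Hsd3b5 (-3.57), Scnn1b (-3.49), Atp5g3 (-3.38) and Zfp932 (-3.32). At Zfp932 the MC38 PBS libraries had 0 scaled tags except replicate 4 with 9.51, so that difference rests on values near the floor. C26 exceeded 8025 at Zmynd8 (1.76), Nsmce2 (1.65), As3mt (1.63) and Lrrc32 (1.6), and was below it at Sntg2 (-2.94), Pak6 (-2.88), Map3k13 (-2.7) and Pus7 (-2.63). Of these named regions 7 of 13, 4 of 9 and 3 of 8 lost their call under at least 1 alternative or left-out library.

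Single libraries stood apart from the other 3 of their group in 28 of 479 groups of values tested, where chance gives 24. Replicate 3 of 8025 cachexia was high at Arap3 (126 against 91.3 to 96.7 scaled tags), Map3k13 (40.8, 21.6 to 23.7), Fosb (142, 35.6 to 44.1), Nr5a2 (117, 67 to 73.7), Acaa1b (11.1, 9 to 9.3) and Cyp4a12a (1.8, 0 to 0.2). C26 PBS replicate 4 stood apart at Olfr173 (34.2, 41.5 to 42), Lrrc32 (37.7, 25.1 to 27.2), Per2 (11.4, 14 to 14.5) and Gsta1 (59.6, 72.3 to 74). C26 PBS replicate 1 did so at Pck1 (264, 229 to 234) and Fos (85.5, 64.1 to 67.1), replicate 2 at Btg2 (6.4, 10.1 to 10.6), and replicate 3 in its promoter share of tags (33.5%, 34.5 to 34.7). C26 cachexia replicate 2 was high at Bhmt (57.5, 38.7 to 40.6, and 30.8, 13.2 to 15.7) and Il6ra (29.9, 22.8 to 23.4). Replicates 1, 3 and 4 of that group stood apart at Nr1d2 (369, 398 to 404), Gclm (29.1, 17.5 to 18.2) and Pck1 (338, 292 to 299). Further values were Cux2 in pre-cachexia replicate 2 (15.8, 8.24 to 9.25), Rasgrp3 in NC26 tumor replicate 3 (80.1, 38 to 41.7), Apcs in NC26 PBS replicate 3 (27.9, 15 to 16.2), and Irf1 (87.8, 62.5 to 66.4) and C4b (77.5, 64 to 65.9) in NC26 PBS replicate 4. In MC38 they were Nr1d1 (247, 188 to 194) and Nr1d2 (466, 371 to 383) in tumor replicate 1, and Zfp932 (9.51, 0 to 0) in PBS replicate 4.

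Other splits were fitted on the libraries of the groups compared, without the library series. For region counts, only 1 of 35 splits, the real one, reached the real count in C26 cachexia (28835, highest other 4), pre-cachexia (3612, 366), cachexia against pre-cachexia (12245, 8) and 8025 cachexia (24674, 5). These margins were wide, so chance is unlikely there, although 35 splits allow no share below 1 of 35. In NC26 the real split also ranked first (59, 29), but by a small margin. Its main count of 333 ran from 80 to 1184 with 1 library left out, so this rank alone does not exclude chance. In MC38, 2 of 35 splits reached the real 20 and the highest other called 315, so chance cannot be excluded. That split (tumor replicates 1 and 4 with PBS replicates 3 and 4) may reflect a structure of the samples whose source was not tested. It followed the library series in part, since all its libraries but tumor replicate 1 belonged to series B. The split wholly along the series called 0 regions. The differences were reached by 1 of 100 splits for C26 minus NC26 (3154, 15) and 8025 minus MC38 (3449, 1120), so chance is unlikely there. For C26 minus 8025 it was 2 of 100 (463, 858). That share was below the limit set beforehand, but 1 other split called more regions, so chance is not excluded. Some of the randomly drawn splits for C26 minus 8025 repeated each other. Numbers of gene lists called did not exclude chance in any comparison. As many lists were called by 2 of 35 splits in C26 cachexia (8, highest other 8), 3 in pre-cachexia (7, 8), 3 between these stages (8, 8), 6 in 8025 (9, 12), 3 in NC26 (9, 10) and 9 in MC38 (6, 8). For the differences it was 24 of 100 (5, 12), 17 (8, 12) and 16 (7, 11). With the preset correlation, other splits thus called as many lists. Splits that exchange 1 library keep part of the real contrast, so they are no clean measure of chance. The other 8 in C26 cachexia came from cachexia replicate 1 with PBS replicates 1, 2 and 3 (acute phase median -0.39). The 12 in 8025 came from cachexia replicate 1 with all PBS libraries (-0.57). A more mixed 8025 split, cachexia replicates 1 and 2 with PBS replicates 1 and 4, also called 9 (-0.10). The acute phase median exceeded all other splits in size in C26 cachexia (0.80, highest other 0.47) and 8025 (0.72, 0.57). It did so by small margins in pre-cachexia (0.35, 0.33) and between these stages (0.43, 0.41), but not in NC26 (0.19, 0.19) or MC38 (0.22, 0.24). In pre-cachexia it was -0.03 to 0.01 where replicate 3 was exchanged with a PBS library, and 0.30 to 0.33 where replicate 2 was. The pre-cachexia median thus depended much on replicate 3.

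Regions called in the cachexia models moved in part the same way in the weight-stable tumors. Of those called in C26 cachexia, 73.0% of the higher and 73.7% of the lower regions had the same sign in NC26, and in MC38 69.6% and 57.3%. Of those called in 8025 cachexia, 78.2% and 68.3% did in MC38. MC38 tumor replicates 1, 2 and 4 scored 0.32, 0.19 and 0.25 over regions called in C26 cachexia, above the PBS libraries of that cohort (-0.17 to 0.09). Replicate 3 scored -0.01, within those PBS libraries. In NC26 the median log2 change of regions called higher exceeded that of regions called lower by 0.34 (highest of the other splits 0.31). In MC38 this gap, over regions called in 8025 cachexia, was 0.35 (highest of the other splits 0.31). A tumor response shared with cachexia may explain this in NC26, and the values it needs were there. The shallow NC26 tumor replicate 1 is argued against as the cause, since without it the gap was 0.34 (highest other 0.30). A difference between library series is argued against by the design, since each series held as many tumor as PBS libraries of these cohorts. Within series A and B the gaps were 0.35 and 0.338 in NC26, and 0.388 and 0.32 in MC38 over regions called in 8025 cachexia. A shared effect of carrying any tumor stays open as a hypothesis, found and tested on the same libraries.

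Promoters were over-represented among regions that rose in C26 cachexia (14.4%, and 12.7% of unchanged regions) and under-represented in both directions in 8025 cachexia (5.59% and 9.07%, and 13.0% of unchanged regions). The C26 excess was absent among changes of at least 1 on the log2 scale (3.93%). A trend of fold change with signal strength may explain the C26 excess, since with loess offsets the promoter share of regions that rose in C26 was 9.95%, below that of unchanged regions. This test cannot decide it. Promoters were 12.2% of regions with 34.3% of region tags in C26 PBS, so offsets by signal could also remove a real promoter rise. Scaling between libraries could contribute and cannot be told apart, since library totals alone gave 12.7%, close to the unchanged share. No biological explanation of this pattern was tested.

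Macrophage marker regions were higher in 8025 cachexia, with a list median of 0.62 (largest absolute value of the other splits 0.50). That other split set cachexia replicate 4 and all PBS libraries against the remaining cachexia libraries, so it kept much of the real contrast. Their list call was lost with an estimated correlation (adjusted p = 0.29), and most of the list's regions did not pass. The rise may reflect more macrophage nuclei among the purified nuclei. At promoters of 5 of 16 marker genes the median change was 1.03. PBS levels at these promoters were 2.9 to 4.74 scaled tags, beside a median of 137 at hepatocyte identity promoters, and the purification by an Albumin-Cre tag would remove such nuclei. Fewer hepatocyte nuclei with all other cell types raised alike cannot be told apart at such low marker levels. The macrophage median exceeded the highest of 4 other marker lists by 0.52. Among the other splits the highest such value was 0.26. A value of -0.57 came from cachexia replicate 2 and all PBS libraries set against the remaining cachexia libraries. That split kept much of the real contrast with its sign turned, so it is no measure of chance. A change of these loci within hepatocytes stays open, as untested. The gene regions C1qc (1.42 ± 0.42 SE, adjusted p = 0.018) and Fcer1g (1.26 ± 0.42, adjusted p = 0.038) were weak. C1qc did not pass without PBS replicate 2 (adjusted p = 0.22) or cachexia replicate 2 (0.056), and Fcer1g without PBS replicates 1 (0.063) or 2 (0.33) or cachexia replicates 1 (0.1), 2 (0.053) or 3 (0.077).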

How the results depend on the processing

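The alternatives chosen only after the result was seen were edgeR on read ends, pseudocounts of 0.5 and 5, array weights, a mean value of 10 or more, non-overlapping regions, and other scalings or the promoter covariate for the promoter share; the rest were chosen before.

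In C26 and 8025 cachexia, of 31 and 30 named regions, 3 and 8 lost their call or changed direction under some alternative or left-out library. Of the list examples 0 of 29 in C26 and 2 of 27 in 8025 cachexia did. In pre-cachexia 1 of 14 named regions and 11 of 22 examples did, between the C26 stages 6 of 16 and 0 of 27, in NC26 9 of 13 and 8 of 8, and in MC38 8 of 10 and 3 of 3. Of 48 list calls 39 were lost under some alternative, among them 7 of 9 in C26 cachexia and 6 of 9 in 8025 cachexia with an estimated correlation. Small changes were mostly not called in the simulation: planted changes of 1.5-fold in C26 libraries were called in 8.5% of regions. With 260 calls its adjustment was stricter than in C26 cachexia with 24838, so this share does not carry over to the real comparison. Tumor replicate 1 of NC26 had 3.47 M tags, and the effect of depth itself was not tested. Motif shares were not run because they need a genome sequence. Where no cause is named below, the cause was not tested.

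A stricter threshold of 0.01 gave, by construction, fewer regions: 13755 in C26 cachexia, 767 in pre-cachexia, 3947 between these stages, 11381 in 8025, 85 in NC26, 8 in MC38, and 1006, 822 and 26 in the differences C26 minus NC26, 8025 minus MC38 and C26 minus 8025. It left 5108 regions shared by C26 and 8025 and 660 shared by pre-cachexia and cachexia. A log2 change of at least 1 in both left 5475 and 1025. DESeq2 gave 4659 in pre-cachexia, 249 in MC38, 6.0e+03 for 8025 minus MC38 and 799 for C26 minus 8025, and edgeR 145 in NC26. Only the cohorts compared gave 4019 in pre-cachexia, 78 in NC26, 10 in MC38 and 434 for C26 minus 8025. Array weights gave 5836 in pre-cachexia, 155 in NC26, 51 in MC38, 4745 for 8025 minus MC38 and 905 for C26 minus 8025. The promoter covariate gave 4355 between the C26 stages, 12 in MC38, 2195 for C26 minus NC26 and 17 for C26 minus 8025. Library series A alone gave 131 in NC26 and 16 in MC38, and series B alone 11 in MC38, each with fewer samples. A pseudocount of 5 gave 4614 for 8025 minus MC38 and 732 for C26 minus 8025, a pseudocount of 0.5 gave 108 for the latter and a mean value of 10 or more 115. An estimated correlation left 9 gene lists.

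Replicate numbers did not pair the samples. Correlations of libraries with the same number, after removing group means, were -0.191 to 0.106 in C26, -0.012 to 0.169 in NC26, -0.26 to 0.044 in MC38 and -0.088 to 0.074 in 8025, and 8 of 35 libraries correlated best with their own number. A replicate block gave 24480 regions in C26 cachexia, 2205 in pre-cachexia, 9102 between these stages, 16015 in 8025, 294 in NC26, 45 in MC38, and 3552, 2087 and 63 for the 3 differences.

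Leaving out 1 library gave 18901 to 22301 regions in C26 cachexia, 861 to 2494 in pre-cachexia, 4347 to 10150 between these stages, 12915 to 18853 in 8025, 80 to 1184 in NC26 and 8 to 67 in MC38. The differences ranged from 2135 to 4579, 1139 to 3692 and 64 to 407, and called gene lists from 43 to 50.

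The promoter share of regions that rose in C26 cachexia fell below that of unchanged regions with a log2 change of at least 1 (3.932%), loess offsets (9.945%), library totals (12.65%) and the promoter covariate (8.506%). The gluconeogenesis list in pre-cachexia changed direction with only regions within 1 kb of the start site (adjusted p = 0.93). Changes near 0 that did not pass changed sign. In 8025, Nr1d2 was 0 with loess offsets, a replicate block and the promoter covariate. In NC26, Nr1d1 was -0.01 with array weights, and Nr1d2 was 0 with loess offsets and only the cohorts compared, 0.05 in series A and 0.02 with a mean value of 10 or more. In MC38, Nr1d1 was -0.03 in series B, Nr1d2 0.02 with loess offsets and the promoter covariate and 0.03 in series A, and Lbp -0.3 in series B and -0.04 with array weights. Leaving out 1 library, these changes ranged from -0.09 to 0.01 (8025 Nr1d2), 0 to 0.11 (NC26 Nr1d1), -0.04 to 0.04 (NC26 Nr1d2), -0.09 to 0.1 (MC38 Nr1d1), -0.12 to 0 (MC38 Nr1d2) and -0.09 to 0.12 (MC38 Lbp).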
